A study of Drosophila melanogaster with 2 samples.

How the data were processed

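RNA that co-precipitated with the protein Syp was sequenced from 2 biological replicates of Drosophila melanogaster S2R+ cells, with 1 library per replicate and both in 1 group. No input, mock or control library was analysed here, so no value is an enrichment over background and no test between groups was made.

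Per the labels, the RNA was fragmented chemically. The deposited signal files give, per their descriptions and names, the normalized signal of all reads on the fly genome build dm3 as 1 bedGraph per library, each made from 1 alignment file. Replicates were not pooled. The aligner, its settings for reads with several matches and the handling of strands are not given in the sources used here. Each deposited signal value was a whole multiple of the smallest value in its file (100% of stretches, within a tolerance of 1e-06). The smallest value was 0.160 in replicate 1 and 0.171 in replicate 2, which is 1000000 divided by the number of alignments of 50 bases that the file sums to. The signal is therefore coverage per 1000000 alignments, with 1 file per library and no split by strand. Stretches of depth 1 that touched no other stretch were 50 bases long in 95.0% of 86284 cases in replicate 1 and in 94.5% of 85995 cases in replicate 2, which sets the alignment length. The recovered depth was 6245455 alignments in replicate 1 and 5846768 in replicate 2. A count of 0 in any bin allows up to 3 alignments, or 0.480 ppm (alignments out of each 1000000) in replicate 1 and 0.513 ppm in replicate 2. These limits and all counting intervals cover counting error only, since no molecular identifiers are given in the sources used here.

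Coverage was summed in 1 kb bins over all 14 sequences of the files and divided by 50 to give alignments, then by the library total to give ppm. An alignment that spans a bin edge or a splice junction adds a part to each bin. The 6 major arms are 2L, 2R, 3L, 3R, 4 and X. U holds unplaced sequence, the 6 sequences with names ending in Het hold mapped heterochromatin, and M is the mitochondrial genome. Ratios between replicates were taken as log2 of the values with a pseudocount of 0.160 ppm. High-signal regions were 1 kb bins at or above the 99th percentile of bins with signal in a library, merged where adjacent. Regions of both replicates that overlapped by at least 1 bp were counted as shared and described over their union. Values are means ± SD of the 2 replicates. With 2 libraries of 1 group, the SD rests on a single difference and no p-value was computed between libraries.

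The plan set before the data were examined also held gene signals, gene lists and transcript features, for use with an annotation of dm3. The gene table at hand is of Release 6, another build, so those parts were not run, no gene is named, and items are given by dm3 coordinates, counted from 1. The items named were fixed by rule at the same time: the 20 shared regions of highest mean signal per base, the 3 highest on each major arm, and the 5 bins furthest apart between replicates in each direction among bins at or above the median of bins with signal. Any other item was chosen after its values were seen and is said to be so.

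The alternatives planned were bins of 100 bp and 10 kb, a pseudocount 10 times higher, the major arms alone, no filter on dim bins, scaling to the major arms or to the median bin, a stricter percentile that keeps the top 0.1% of bins, a reciprocal overlap of 50%, 1 threshold for both libraries, capped coverage and each replicate alone. Scaling of the named regions, regions without U and Het, the named regions in each replicate alone and all tests on steps, gaps, shapes and stacks were added after seeing the data. The bin comparison was tested on simulated data drawn from the real bins: of 200 bins of at least 200 alignments changed 4-fold, among 139656 bins, 200 passed a 2-fold difference in the right direction, and 0 of 8126 unchanged bins of that depth did. The draws held counting error alone, around a common profile for both libraries. They do not show how the comparison behaves in bins under 200 alignments or under the spread between real libraries. The gap search found 240 of 240 simulated gaps at their true length. All simulated reads were spliced and no background was added, so this shows only that the search works on clean gaps. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.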

Results

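RNA immunoprecipitation followed by sequencing (RIP-seq) was used to ask which RNAs are recovered with Syp, the fly homologue of the RNA-binding protein Syncrip, from S2R+ cells. S2R+ is an adherent derivative of the Schneider 2 line, which was made from fly embryos and has features of blood cells. The labels list Syp with a C-terminal HA tag and with a FLAG tag, under the promoter of the metallothionein gene MtnA, which copper switches on. They do not say whether both were in the same cells. The cells received copper(II) sulfate at 0.35 mM for 24 hours. The 2 biological replicates held 6245455 and 5846768 alignments of 50 bases and covered 24.0 and 22.9 Mb of dm3 with at least 1 alignment. The 2 libraries were distinct: over 36006 bins of 1 kb with at least 10 alignments, a chi-square comparison gave 6.72 per degree of freedom, against about 1 for repeated sampling of a single library, and 2.93 over the 35071 such bins of the major arms.

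The first question was where in the genome the recovered RNA mapped. The 6 major arms took 63.7% ± 3.0 (SD, n = 2) of the alignments. Unplaced and heterochromatic sequence together took 30.8% ± 3.7, most of it on U, with 24.1% ± 1.2. The mitochondrial genome held 5.47% ± 0.77. The sequence XHet, only 0.196 Mb to its last covered base, held 5.86% ± 2.61, and this mean hides a large difference, with 4.01% in replicate 1 and 7.71% in replicate 2. Each of the 6 arms and M had a lower share in replicate 2 than in replicate 1, while U and XHet had a higher share, so part of each fall on the arms is the counterpart of the rise on U and XHet in values that sum to a fixed total. Coverage of U was sparse in spite of its share, with 0.91% ± 0.03 of its bases covered.

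**Figure D1:**
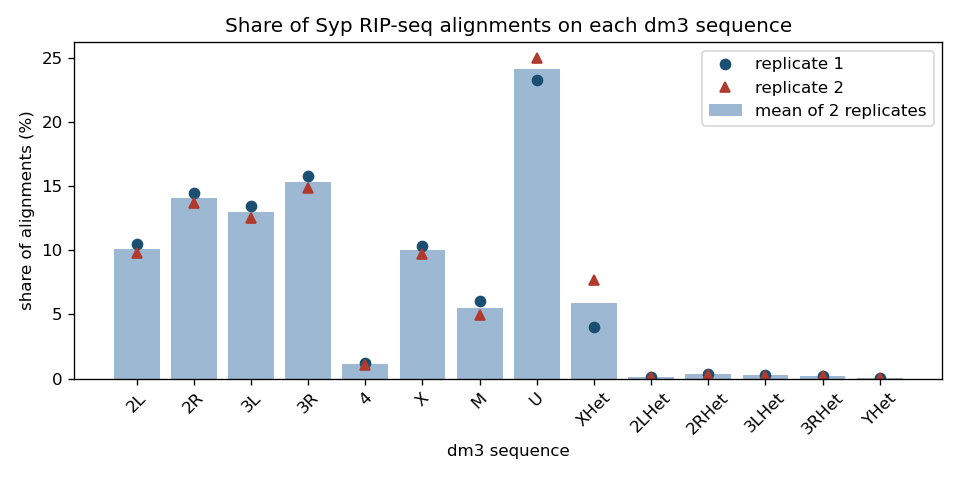
Share of all alignments (percent, vertical axis) on each of the 14 dm3 sequences (horizontal axis), with the mean of 2 replicates as bars and each replicate as a point. U holds the largest single share, 23.3% and 24.96% in the 2 replicates, and XHet differs most between them.

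Relative to length, chromosome 4 gave the densest signal of the major arms. It carried 8469 ± 869 ppm (alignments out of each 1000000) per Mb, and 28.5% ± 1.7 of its bases were covered. Arm 2R followed with 6663 ± 258 per Mb and 21.6% ± 0.7 of bases covered. Arms 3R (5490 ± 250) and 3L (5302 ± 270) came next, and within each library 3R lay above 3L, by 188 ± 20 per Mb. The X chromosome (4475 ± 209) lay above 2L (4400 ± 211) by 74.4 ± 2.7 within libraries, but below it by 195 ± 28 once coverage was capped at the level of the top 0.1% of bins. Outside the major arms and M, U and XHet lay far above every arm, at 23993 ± 1204 and 299076 ± 133288 per Mb. The heterochromatic sequences 2LHet, 2RHet, 3LHet and 3RHet lay lower than the arms, at 2441 ± 167, 966 ± 88, 935 ± 60 and 830 ± 99 per Mb. YHet carried the least, 14.7 per Mb in each replicate, with 0.097% and 0.168% of its bases covered in replicates 1 and 2. It held only 0.0005% of the alignments of each library, too few to read anything from the near equality.

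A small part of the genome held most of the signal. The top 1% of the 68630 bins with signal held 56.0% ± 2.8 of all alignments, and the top 0.1% held 40.6% ± 3.2. On the major arms alone the signal was less concentrated, with 32.7% ± 1.2 in the top 1% and 11.8% ± 0.9 in the top 0.1%.

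The high-signal regions were then called in each replicate. Replicate 1 gave 383 and replicate 2 gave 388, from thresholds of 141 and 135 ppm per bin, and 337 were shared, which is 88.0% of those of replicate 1. Of the 337, 307 lay on the major arms, with 88 on 3R, 73 on 2R, 58 on 3L, 43 on 2L, 41 on X and 4 on chromosome 4. U held 19, XHet 3 and M 2. The 20 regions with the highest mean signal per base took 36.4% ± 3.0 of all alignments. Of these 20, 10 lay on U, 3 on XHet, 2 on M and 5 on the major arms.

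The 3 highest regions were all outside the arms. The region at U 5726001 to 5728000 held 103849 ± 4027 ppm, and 90% of its signal lay on 387 bases. The region at U 9063001 to 9065000 held 64436 ± 8908, with 90% on 100 bases. The region at XHet 190001 to 192000 held 41249 ± 24579, and replicate 2 was 2.46 times as high as replicate 1, with 58629 against 23869. The other U regions among the 20 began at 9660001 (17449 ± 1492), 4570001 (15578 ± 1060), 6962001 (15229 ± 2865), 3545001 (4525 ± 113), 8839001 (3569 ± 738), 5301001 (3459 ± 560), 9578001 (3141 ± 261) and 8595001 (1824 ± 702), and in each of them between 46 and 106 bases held 90% of the signal. On XHet, the regions at 184001 to 185000 (10509 ± 1018) and 194001 to 195000 (6640 ± 527) differed less between replicates than the one at 190001.

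On the mitochondrial genome the calls of both replicates merged to 2 long regions. M 11001 to 15000 held 30731 ± 6480 ppm, and replicate 2 was at 0.74 of replicate 1. M 1001 to 9000 held 23769 ± 1139, but its bin at 6001 to 7000 held 201 ppm in replicate 1 and 38.3 in replicate 2, below the threshold of replicate 2. Within M, where bins were chosen after their values were seen, the bin at 12001 to 13000 held 25.9% ± 1.4 of mitochondrial alignments, the bin at 2001 to 3000 held 21.0% ± 1.6 and the bin at 13001 to 14000 held 19.2% ± 1.7. The bin at 10001 to 11000 held 0.06% ± 0.03. Between 15001 and 17000 neither replicate had an alignment, which allows up to 0.480 and 0.513 ppm per bin.

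On the major arms, 5 regions ranked among the 20. The region at 3L 2113001 to 2114000 was by far the strongest, with 8877 ± 458 ppm, nearly 4 times the next arm region per base, and 90% of its signal fell on 101 bases around position 2113388. The region at 2R 19932001 to 19933000 held 2263 ± 94, in 3 blocks separated by stretches of almost no coverage. The region at 2R 1645001 to 1646000 held 2027 ± 234 and that at 2R 5995001 to 5996000 held 1776 ± 238. The region at 3R 5609001 to 5611000 held 3205 ± 441, with its deepest base at 5609963, and consisted of 2 high blocks with a gap between them and a low shoulder.

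Next on 3R came the region at 3300001 to 3301000, with 1522 ± 910. Replicate 2 was 2.47 times as high there, 2166 against 878. The third on 3R was at 16617001 to 16619000, with 2273 ± 161. On X the highest were 5796001 to 5799000 (4749 ± 787), 3439001 to 3441000 (2072 ± 535) and 9046001 to 9049000 (2781 ± 6). The second of these was compact, with 90% of its signal on 108 bases, while the other two spread it over 1264 and 1426 bases. On 2L the regions at 22240001 to 22241000 (1091 ± 35), 22247001 to 22248000 (920 ± 31) and 21626001 to 21630000 (2467 ± 3) differed between replicates by under 10%. On 3L the second and the third were 6252001 to 6254000 (1907 ± 241) and 9367001 to 9368000 (942 ± 24). Chromosome 4 had 1053001 to 1056000 (1870 ± 106), 87001 to 88000 (508 ± 74) and 341001 to 342000 (188 ± 27), the last of these ranking at 236 of 337. For the 307 arm regions together, the median number of bases holding 90% of the signal was 746, and 30 regions had 300 or fewer.

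**Figure D2:**
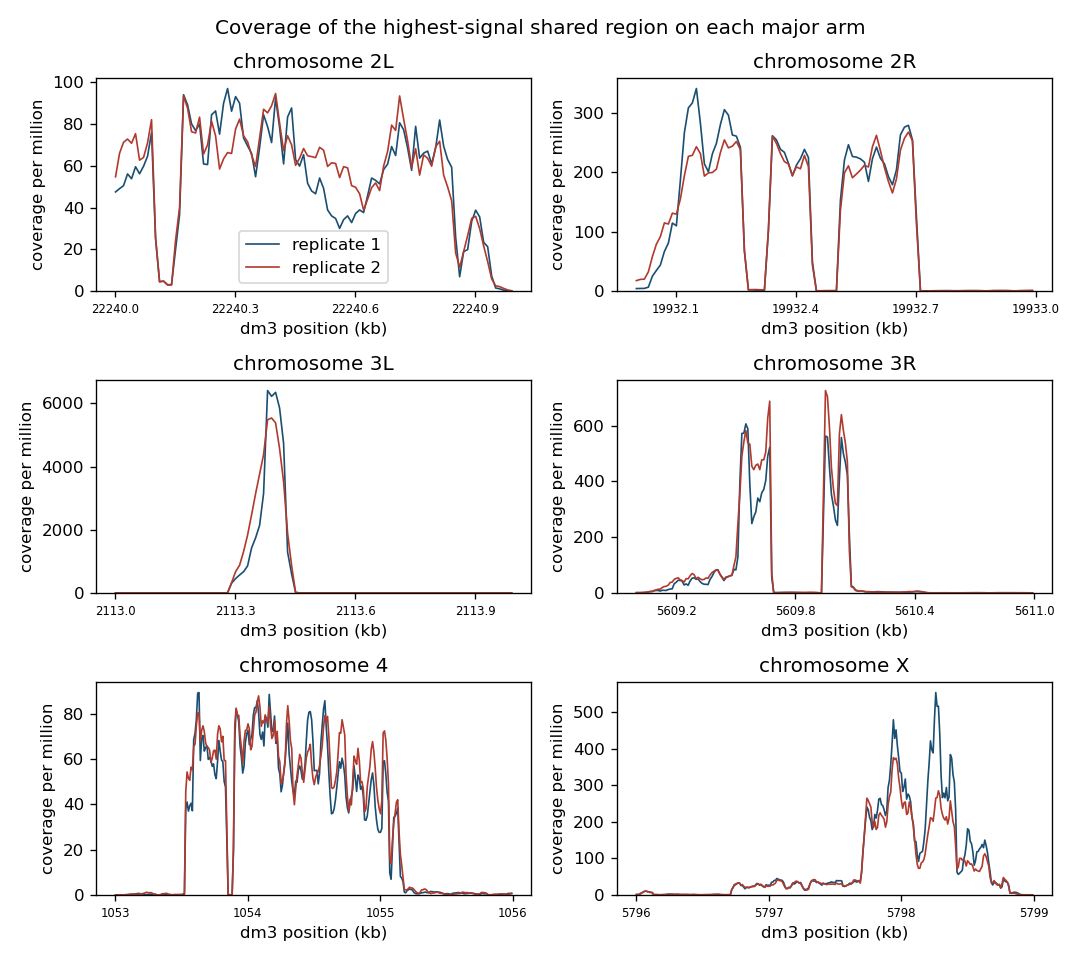
Coverage per 1000000 alignments (vertical axis, from 0, a scale of its own in each panel) along the shared region of highest mean signal on each of the 6 major arms (horizontal axis, dm3 position in kb), in steps of 10 bases for each replicate. The 3L region is a single narrow peak, while the 2R, 3R and chromosome 4 regions are blocks with sharp edges at the same positions in both replicates.

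The last comparison was between the replicates. Across the 68630 bins with signal, log2 values correlated with Pearson's r = 0.9497 and Spearman's rho = 0.907. These describe agreement across bins, which are not independent replicates. The median log2 ratio of replicate 2 over replicate 1 was -0.12, and the SD over bins was 0.82, against 0.30 in the 3432 brightest of the 34315 bins at or above the median. Of those 34315 bins, 1763 (5.14%) differed by more than 2-fold, 536 higher in replicate 2 and 1227 higher in replicate 1. Scaling to the major arms changed this split to 725 and 884, and scaling to the median bin changed it to 833 and 749. Splitting each bin's alignments at random between the libraries gave 1073 such bins on average and at most 1132 in 100 draws. The split used the overall share of each library, so it lacks the median log2 ratio of -0.14 in these bins. With the scalings to the major arms and to the median bin, which reduce that offset, 1609 and 1582 bins differed. The random split holds counting error alone, with alignments taken as independent molecules, and separate libraries would exceed it in any case.

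Regions count as shared only when they pass the threshold in both replicates, which can leave out regions that differ strongly, and 383 and 388 were called in all. The ratios of regions called in only 1 replicate were not examined. Of the 337 shared regions, 3 had over 2-fold more signal in replicate 2 and 0 had over 2-fold more in replicate 1, and with 1 library on each side this has no test. The 3 were XHet 190001 to 192000, 3R 3300001 to 3301000 and, chosen after its values were seen, U 4305001 to 4306000, with 142 and 383 ppm in replicates 1 and 2. The bins furthest apart by ratio were dim. The bins at 2L 15046001, 2RHet 1769001, 2R 17623001 and 3L 24252001 had 14, 13, 12.94 and 12.52 alignments in replicate 1, by summed coverage, and 0 in replicate 2. Against the 3 alignments that a count of 0 allows, with the value of replicate 1 taken as measured, replicate 1 was at least 4.37-fold, 4.06-fold, 4.04-fold and 3.91-fold higher. The bin at 3R 15660001 had 21 alignments against 1, a ratio of 19.7 (95% exact interval 3.16 to 813). In the other direction, U 9074001 had 2 against 27, a ratio of 14.4 for replicate 2 over 1 (3.62 to 125), and U 3925001 had 7 against 58, a ratio of 8.85 (4.03 to 22.99). The bins at X 6756001 (1 against 16), 2R 19798001 and 3L 16144001 (each 1 against 13) completed the 5. The intervals cover counting error only, and these 10 bins were selected as the most extreme of 34315.

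**Figure D3:**
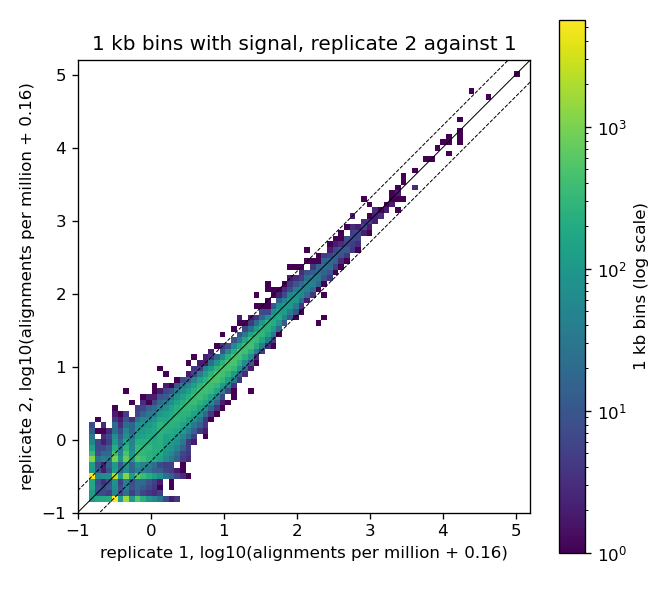
Signal in ppm in 1 kb bins with signal, replicate 2 (vertical axis) against replicate 1 (horizontal axis), both as log10 after adding 0.16, with colour giving the number of bins on a log scale. The solid line marks equality and the dashed lines a 2-fold difference, and the scatter is widest among dim bins.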

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

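The scaling of named regions, their values in each replicate alone and the count without U and Het were chosen after seeing the data. Each replicate alone kept all 16 chromosome shares, both concentration values and the 33 named regions within 1 SD of the mean, as 2 values must, so this says nothing about stability. Counts and correlations that need both replicates had no such value. Scaling to the major arms left the 33 regions within 1 SD. This scaling moves the 2 replicates in opposite directions around their mean. The mean could hardly change, so the result says little about stability either. The number of shared regions, 337, stayed within 1.5 times under a reciprocal overlap of 50%, 1 threshold for both libraries and without U and Het. A reciprocal overlap could change it little, since regions are whole 1 kb bins. Leaving out U and Het could also change it little, since 307 of the 337 lay on the major arms. The number of shared regions became 39 when only the top 0.1% of bins passed, which is fewer bins by construction, and 898 in 100 bp bins. The number of bins over 2-fold apart, 1763, stayed within 1.5 times under both scalings. It was 20653 with no filter, which adds the dimmer bins, and 161 with 10 times the pseudocount, which shrinks ratios of dim bins. In 100 bp bins it was 35989, or 17.2% of 209608 bins against 5.14% of 34315, and the cause was not tested. Pearson's r, 0.9497, stayed inside its block bootstrap interval of 0.948 to 0.952 on the major arms. It was 0.884 in 100 bp bins, 0.981 in 10 kb bins, 0.985 with 10 times the pseudocount and 0.964 over bins at or above the median, and the cause was not tested. Capping coverage at the level of the top 0.1% of bins moved all 16 shares and took the major arms to 97.1%, U and Het to 2.28% and M to 0.595%. Both concentration values were within 1 SD in 100 bp bins, while on the major arms alone the top 1% of bins held 32.7% and the top 0.1% held 11.8%. Gene signal, gene list and transcript feature alternatives were not run. Depth limits dim bins: among the 3432 faintest at or above the median, 18.2% differed over 2-fold.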

Other observations

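All tests in this part were added after the data were seen, and those of steps, permuted clusters and stacks were chosen after their results were known. On the major arms coverage often changed abruptly. From at least 20 alignments, depth fell to 20% or less within 1 base at 3163 positions in replicate 1 and 2767 in replicate 2, and 2398 of these falls were at the identical base in both. Gaps were taken from a fall to the next rise among the steps shared by both replicates. Steps seen in only 1 replicate were left out, so a gap can run across them, and no limit was set on length. This gave 2262 gaps, and 1170 of them (51.7%) were 40 to 100 bases long. These short gaps had a median of 63 bases and a middle range of 59 to 69. By arm the median was 62 on 2L and 2R, 63 on 3R, 64 on 3L, 57.5 on chromosome 4 (24 gaps) and 68 on X (122 gaps). X also had the lowest share of gaps in this range, 43.3% against 45.2% to 61.9% on the other arms. Its median over gaps of any length was the longest, 140 bases against 73 to 126.

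A hypothesis is that these gaps are introns crossed by spliced alignments and that short ones are longer on X, which was singled out after the medians were seen. With the falls of replicate 2 placed at random among the bases of depth 20 or more in their 1 kb bins, at most 30 were shared in 100 draws, against 2398 observed, which argues against steps placed by chance. Any edge that recurs in both libraries would pass this test, so it does not tell introns from other edges. Shared falls were also common outside the arms, with 44 of the 54 of replicate 2 on U and 11 of 15 on M. With gaps within 10 kb joined to clusters, the mean was 68.8 ± 7.2 bases (SD, 70 clusters) on X and 65.2 ± 7.7 (488 clusters) on the autosomes, a difference of 3.59 ± 0.92 bases (SE), two-sided permutation p = 0.00034 over clusters, or 0.0021 when the largest contrast of any of the 6 arms, scaled for its number of clusters, is taken in each of 100000 resamples; chromosome 4 departed further in bases, by -6.17 from the other arms, with 11 clusters. Within 4 classes of flanking depth the difference between X and autosomes was 3.26 bases (permutation p = 0.00094), which argues against depth. From each replicate alone it was 3.38 and 4.05, but most falls were at the identical base in both, so these values are not independent. Steps from at least 10 alignments gave 3.42 ± 0.67 with permutation p = 1e-05, the smallest possible here, from 140 clusters on X. Steps from at least 50 alignments gave 2.84 ± 1.47 with permutation p = 0.099 from 28 clusters on X. These sets of steps overlap, so they are not independent. A biological difference between X and autosomes stays open as untested, since splice sites were not examined here.

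Replicate 2 was higher relative to replicate 1 in compact bins than in spread-out ones. Among arm bins of at least 20 ppm, the mean log2 ratio was -0.004 in 665 bins with 90% of their signal on 300 bases or fewer and -0.24 in 900 bins that spread it over more than 800, a difference of 0.24 ± 0.02 (SE over bins, which are not replicates), and it was above 0 on each of the 6 arms. At 100 ppm or more the difference was 0.26 ± 0.04, which argues against counting noise in dim bins. More unspliced RNA or DNA in replicate 1 would put more depth inside the gaps there. For 2171 of the gaps found, with a length limit of 5000 bases, depth inside relative to their sides was higher in replicate 2. The difference was 0.15 ± 0.06 on the log2 scale (SE from 1000 resamples, with 1 library on each side). Gaps were kept only where depth fell to 20% or less in both replicates, which leaves out places with much depth inside. More unspliced RNA or DNA in replicate 1 at such places is therefore not decided by this comparison. A difference in RNA fragmentation or size selection between the libraries may account for the pattern and was not tested; no biological explanation was tested.

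Among islands with at least 2000 alignments in both libraries together, the median length was 117.5 bases for 38 on U and Het, 99 for 19 on M and 894 for 420 on the major arms. The stack at U 9063651 to 9063723, chosen after its values were seen, held 530912 alignments of both libraries on 73 bases. If alignments with several equal matches had been left out upstream, reads across a distinguishing base would remain, but whole alignments of 50 bases inside an island under 100 bases share a base whatever the cause, and such a base was found in all 15 islands of that length on U and Het, all 11 on M and 2 of 3 on the major arms. Of the longer islands, 8 of 23 on U and Het (34.8%) had a base under at least 99% of their alignments, against 0 of 417 on the major arms and 0 of 8 on M, which does not decide, since uniformly cut RNAs would look alike. The opposite, every match of a read reported, would repeat depth profiles, and 0 of 195248 stretches of 200 bases had a profile found elsewhere; without the genome sequence it is unknown which covered stretches are repeated, so both stay open and no biological explanation was tested.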
